A study of Rattus norvegicus with 2 samples.

How the data were processed

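Total RNA from the hypothalamic paraventricular nucleus of 12-week-old male Sprague Dawley rats was measured on 1-colour rat gene expression arrays, per the labels. 1 array held RNA of offspring of vehicle-treated mothers (control), and 1 array held RNA of offspring of mothers given 200 µg/kg dexamethasone in the third trimester. RNA was isolated with TRIzol and a column kit, amplified, and labelled with Cy3 by a low-input kit, per the labels' protocols. Whether an array held RNA of a single animal or a pool is not given in the sources used here.

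The deposited scanner files hold spot intensity on a linear scale. Per the file headers, spots were quantified with Feature Extraction 10.7.1.1, while the submitters' processing notes name version 9.5.1.1. Per the file headers, probe positions are those of the rn4 rat assembly. The processed intensity in the deposited files is the scanner software's background-subtracted value. The deposited value table holds a further processed intensity for each probe, on a linear scale, with a median of 149.9 in both columns. For values above 10, its sorted columns differed by at most 0.0236%, so both arrays had been given nearly 1 distribution. The difference between its columns correlated with that of the scanner values at 0.996 across probes, which settles its direction. How that table was centred and which algorithm made it are not given in the sources used here.

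Each array held 42877 non-control spots for 30367 probes, of which 1390 were spotted 10 times. Spots with an outlier mark (267 control, 249 dexamethasone) were left out, and no spot was saturated. Log2 processed intensities were averaged over the spots of a probe, and the 75th percentile over all non-control probes was subtracted from each array (1404 in the control array and 1480 in the dexamethasone array, as linear signal). All differences are dexamethasone minus control on this scale. A gene took the value of its brightest probe that was well above background on both arrays. Signals quoted as such are processed intensities before scaling. For a gene well above background on 1 array alone, the fold is a bound: the detecting array's scaled value against the higher of the other array's lowest well-above-background signal and the probe's own signal.

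Gene names in the files are those of the array design. They were updated through a table of RefSeq genes of the GRCr8 assembly, used for names alone: 17998 probes were matched by accession, 2662 by current symbol and 559 by older symbol. Another 9148 probes kept the name in the files, which for some is a transcript number and not a gene.

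With 1 array per group there was no test of the treatment, no p-value and no measure of the spread between animals. The only error in the files is that between repeated spots of a probe within an array. The between-array difference of repeated spots had a median SD of 0.041 (log2) over 1314 probes, and 0.21 over the 109 probes with a mean log2 signal below 6. A gene was counted as higher or lower at a 2-fold difference, a size rule and not a test. Both arrays lay on the same slide, at different positions, so position and group cannot be told apart.

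The grouping, the size rule, the gene lists, the named-gene rule and 12 processing alternatives were fixed before the data were examined. The 22 gene lists covered the renin-angiotensin system, DNA methylation, corticosteroid response, peptides and their receptors, transmitter systems, ion channels, sodium handling, redox, immunity, clock, stress and housekeeping genes. The 15 marker lists covered brain cell types, blood, and neighbouring regions. Each list is described by its median difference and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these 2 arrays and is not a test of the treatment. Random-list medians were drawn from genes measured on both arrays. Another 5 lists (pallial neurons, hippocampus, striatum, hypothalamus and a second telencephalic list) were written after the differences had been seen.

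Named genes were chosen by this rule: the 8 genes with the largest positive and the 8 with the largest negative difference among genes measured on both arrays, with a mean value at or above the median of measured genes, a symbol that is not a number or transcript ID, and the same sign with normexp background correction and with quantile normalization; every measured member of the renin-angiotensin and DNA methylation lists; the 3 members with the largest absolute difference in each other list; and the 3 named genes with the largest bound each way among those detected on 1 array. Genes named beyond this rule, to complete a small count or a list or as known products of the nucleus, were chosen after their values were seen.

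The alternatives set in advance were scaling by the median of detected probes, quantile and cyclic loess normalization, normexp background correction (offset 50), no background correction, the deposited value table, the mean over a gene's probes, 3 other filters on dim probes, and thresholds of 1.5-fold and 3-fold. A further 2 were chosen after seeing the data: counts without the telencephalic lists and without probes holding a GAA repeat. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1. Figures were drawn with matplotlib 3.10.9. The steps were tested on simulated data for the dexamethasone against control comparison over 15280 genes. There 100% of the 200 changed genes, set at a log2 change of 1.5 or 2 either way, passed the 2-fold rule, as did 0.00663% of unchanged genes. Of 100 simulated lists with no shift, 4 had a median outside the central 95% of random lists, and a list shifted by 0.5 lay at the 100th percentile. The simulated noise was independent between genes and of the order of the spread of repeated spots. The real differences had an SD of 0.54 over genes. The simulation thus checks the steps and gives no error rate for these arrays. Probe positions in exons or untranslated regions were not analysed here, nor was DNA methylation. Values of some genes that this rule or these lists take in are not reported here, although the counts and medians include them.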

Results

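The series concerns hypertension programmed before birth and DNA methylation of the hypothalamic angiotensin receptor. Gene expression was measured in the paraventricular nucleus, a hypothalamic centre of hormone release and sympathetic outflow, of 12-week-old male offspring of mothers given vehicle or 200 µg/kg dexamethasone, a synthetic glucocorticoid, in the third trimester. There was 1 array per group. In the control array 24139 of 30367 probes (79.5%) were well above background, and in the dexamethasone array 23745 (78.2%). The number of arrays limits the precision: differences below are between these 2 arrays, with no replicate check, and any error given is between repeated spots of a probe.

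The first question was how far the transcriptome of the nucleus differed after prenatal dexamethasone. Among genes of above-median signal, the largest excess in the dexamethasone array was in the following neuronal genes. Itpka, an inositol trisphosphate kinase of dendritic spines, was 36.5-fold higher (log2 difference 5.19), and Neurod2 and Neurod6, transcription factors of cortical and hippocampal excitatory neurons, were 25.3-fold and 21.2-fold higher. Icam5, an adhesion molecule of telencephalic neurons (24.3-fold), Bhlhe22, a neuronal transcription factor (21.3-fold), Hpca, which encodes the calcium sensor hippocalcin (20.8-fold), and Bcl11b, a transcription factor of deep-layer cortical and striatal neurons (log2 difference 4.32), were also among the 8 largest.

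The largest deficits in the dexamethasone array were smaller. Those given here are the largest under the naming rule above, which leaves out genes of below-median signal and symbols that are numbers. In all, 41 measured genes were at least 4-fold lower. Srpk3, a kinase of splicing factors, was 8.84-fold lower and Snhg11, a noncoding host gene of small nucleolar RNAs, 6.09-fold lower (-2.93 and -2.61 on its 2 probes). Avp, which encodes vasopressin, the antidiuretic hormone made in this nucleus, was 3.76-fold lower, with a signal of 3464 against 970.3 (spot SD of the difference 0.039, 10 spots). Casq2, a calcium-storage protein, was 4.11-fold lower, and Lpin3, a phosphatidate phosphatase, 3.82-fold lower. Fbn2, a microfibril protein (3.80-fold), Slc5a7, the choline transporter of cholinergic neurons (3.75-fold), and Map3k6, a stress-activated kinase (3.74-fold), followed.

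Of 15280 genes measured on both arrays, 501 (3.28%) were at least 2-fold higher and 401 (2.62%) at least 2-fold lower in the dexamethasone array, and 14378 (94.1%) lay within 2-fold. At 4-fold the counts were 123 and 41, and at 16-fold they were 18 and 0. Log2 values of the 2 arrays correlated at 0.986 across genes, which are not independent replicates, and the differences had an SD of 0.54. Of 2748 genes with several measured probes, 127 passed 2-fold, 68 of them on all their probes and 12 with probes of opposite sign. With normexp background correction the counts were 290 higher and 162 lower, a split of 64.2% higher among called genes against 55.5%.

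**Figure D1:**
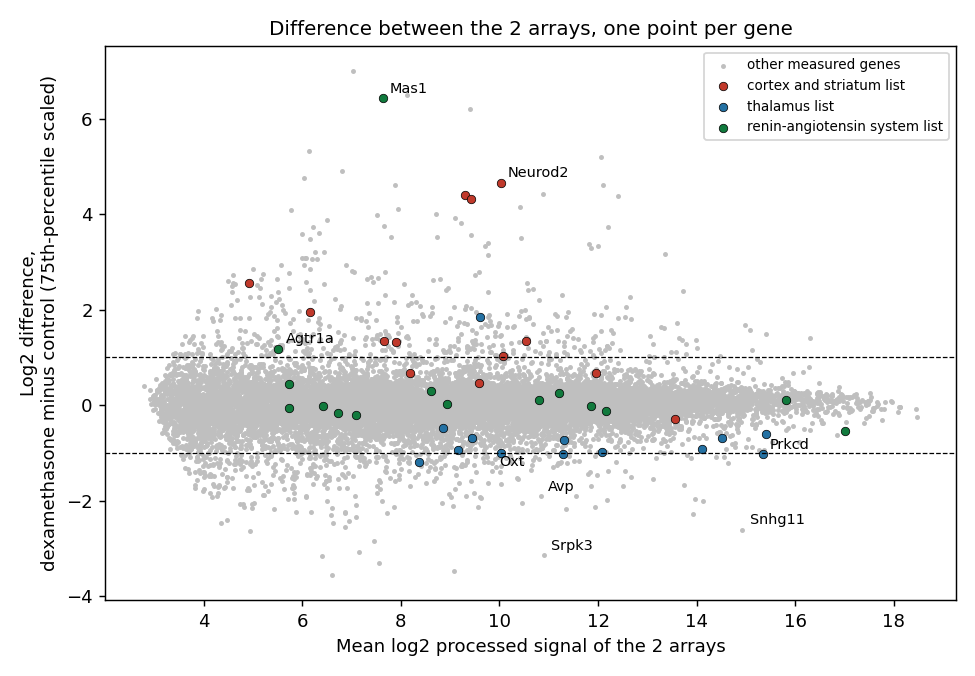
Difference between the arrays against signal. Each point is a gene measured on both arrays, with the mean log2 processed signal of the 2 arrays on the x axis and the log2 difference, dexamethasone minus control, on the y axis; dashed lines mark 2-fold. Most genes lie within 2-fold, while Mas1 (6.43) and Neurod2 (4.66) lie far above and Srpk3 (-3.14) and Avp (-1.91) below.

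The next question was the renin-angiotensin system, since the series title names the angiotensin receptor. Agtr1a, the main angiotensin II receptor of the nucleus and a mediator of its pressor and sympathetic actions, was 2.27-fold higher in the dexamethasone array (log2 difference 1.19). Its probe (rn4 chromosome 17, 40629499 to 40629558) was spotted 10 times, with a mean signal of 29.7 ± 3.25 in the control and 71.1 ± 5.89 in the dexamethasone array (SD over 10 spots). All 10 spot pairs were higher, by 0.88 to 1.47, with a spot SD of 0.19. Agtr1b, its close paralog, was at 0.45, and how far either probe pairs with the transcript of the other was not analysed here, so the split between them is uncertain. Mas1, the receptor for angiotensin-(1-7), was 86.1-fold higher, from a signal of 20.8 to 1884 (rn4 chromosome 1, 42185391 to 42185450). Mas1 is abundant in hippocampus and cortex, and the cortex and striatum marker list was also higher (median 1.33).

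The other 13 measured members lay within 2-fold. Agt, the angiotensinogen gene, in brain expressed mostly by astrocytes, was 1.45-fold lower (-0.54). Ace, the angiotensin-converting enzyme, was at 0.10, and Atp6ap2, an accessory subunit of the proton pump, at -0.01. Peptidases that process angiotensins were at -0.16 (Enpep), -0.06 (Anpep), -0.01 (Mme), 0.02 (Nln), 0.10 (Ctsd) and 0.30 (Lnpep), and the receptor-associated protein Agtrap was at 0.26. Agtr2, the other angiotensin II receptor type, was well above background in the dexamethasone array alone (signal 2.88 against 10.3), with a bound of at least 1.67-fold. Of the 15 measured members 2 were at least 2-fold higher and 0 lower, and the list median was 0.02, the 54.4th percentile of random lists. At signals this low background handling mattered: with normexp correction Agtr1a was at 0.48 and Mas1 at 4.61, and without background correction Agtr1a was at 0.47 (spot SD 0.10), so its 2-fold call ended. Among 1206 genes with a mean signal within 0.5 log2 of that of Agtr1a, 93 (7.71%) differed at least as much either way.

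The DNA methylation machinery was examined because the title names DNA methylation; methylation itself was not analysed here. Dnmt3b, a de novo DNA methyltransferase, was 2.77-fold lower in the dexamethasone array (-1.47; signal 115 against 43.8; rn4 chromosome 3, 144069022 to 144069081). Its sister enzyme Dnmt3a was at -0.14. The TET dioxygenases, which oxidise methylcytosine, were at 0.09 (Tet1), -0.09 (Tet2) and 0.27 (Tet3), and the glycosylase Tdg, which removes its oxidised forms, at 0.04. Methyl-CpG readers were at 0.01 (Mbd1), 0.16 (Mbd2) and 0.27 (Mbd3). The growth-arrest genes Gadd45b, Gadd45a and Gadd45g, tied to DNA repair and demethylation, were at 0.59, 0.30 and 0.18, and the repair endonuclease Apex1 at 0.16. Of 14 measured members 1 was at least 2-fold lower and 0 higher, with a list median of 0.12 (91.1st percentile). Dnmt1, Dnmt3l and Uhrf1 were not well above background on either array, and Zbtb33 in the control array alone. Without background correction Dnmt3b was at -0.84, and it had no repeated spots on the array.

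**Figure D2:**
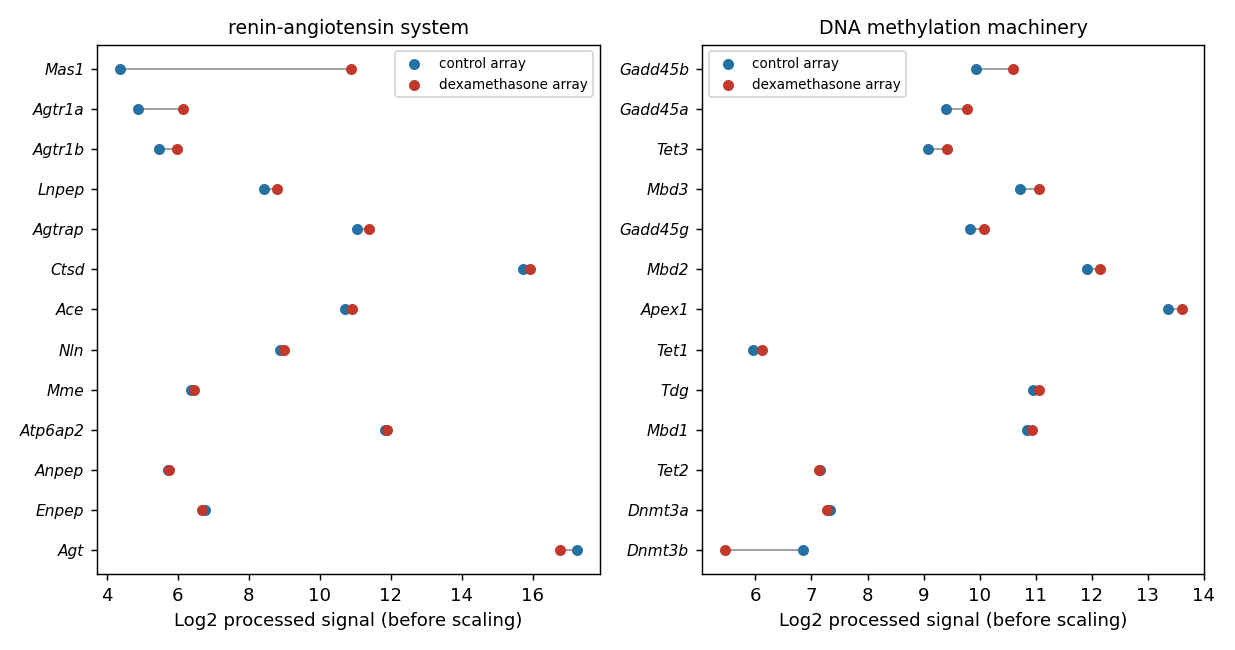
Signals of 13 genes of the renin-angiotensin system (left) and 13 genes of the DNA methylation machinery (right). Each line joins the log2 processed signal, before scaling, of a gene in the control array (blue) and the dexamethasone array (red); Mas1, Agtr1a (log2 difference 1.19) and Dnmt3b (-1.47) are the genes past 2-fold, and no error bar is drawn since there was 1 array per group.

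Peptide genes of the hypothalamus differed in both directions. Together with Avp, the genes of oxytocin (Oxt, 2.61-fold lower), neuropeptide FF (Npff, 3.22-fold lower) and vasoactive intestinal peptide (Vip, -1.06) were at least 2-fold lower in the dexamethasone array. Nmb, encoding neuromedin B, was highest (3.39), followed by Nts, encoding neurotensin (2.06), and Crh, the corticotropin-releasing hormone of the stress axis, was 2.62-fold higher (1.39). Of 24 measured peptide genes 9 were at least 2-fold higher and 4 lower (median -0.04, 16th percentile; -0.21 with no filter on dim probes). Of 12 transcription factors tied to the nucleus, 2 were at least 2-fold higher: Fezf2, which is also a cortical gene (5.32, and 2.93 with normexp), and Nr4a1, an activity-induced nuclear receptor (1.23). Zic1 was at -0.89 and Sim1, which specifies the nucleus in development, at -0.31. The list median was 0.25 (98.7th percentile), and 0.15 without background correction, but the list was mixed, with 7 genes higher and 5 lower. Among 28 peptide receptor genes, Sstr3, a somatostatin receptor (1.73), and Mc4r, the melanocortin receptor of appetite and blood pressure control (1.20, but 0.40 with normexp), were past 2-fold upward. Galr1, a galanin receptor (-1.06 on its brightest probe, -0.86 on the other and -0.73 with normexp), and Mc3r, another melanocortin receptor, were past it downward (list median -0.14, 6.07th percentile; -0.22 to -0.02 over settings). In the same comparison the cortex and striatum marker list had a median of 1.33.

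Markers of the cortex and striatum and of the thalamus differed in opposite directions. Of 13 measured cortex and striatum markers 12 were higher and 9 at least 2-fold higher in the dexamethasone array, with a median of 1.33 (100th percentile), led by Neurod2, Neurod6 and Bcl11b. Of 13 thalamic markers 12 were lower, with a median of -0.91 (percentile 0). Those past 2-fold downward were Gbx2, a thalamic homeobox gene (-1.19), Prkcd, a protein kinase C of thalamic relay neurons (-1.03, spot SD 0.043), and Slitrk6, while Pdyn, encoding prodynorphin, was at 1.84. Lateral hypothalamic markers had a median of 0.67 (99.9th percentile), with Cartpt, the CART peptide gene (1.91), and Pmch, encoding melanin-concentrating hormone (1.20), past 2-fold and Lhx9 at -0.94. This median rested on 5 genes and ranged from 0.13 with no filter on dim probes to 1.20 for bright genes alone. Suprachiasmatic and preoptic markers had a median of -0.39 (0.92nd percentile), with Gnrh1, encoding gonadotropin-releasing hormone (-1.45, and -0.79 with normexp), and Vip lower and Moxd1, a monooxygenase-like gene, higher (4.08, and 1.96 with normexp). Arcuate and ventromedial markers had a median of -0.12 (14.6th percentile), which turned to 0.24 for bright genes alone, with Npy, the neuropeptide Y gene (1.85), and Th, tyrosine hydroxylase of catecholamine synthesis (1.16), higher and Gpr149 at -0.95. Anterior pituitary markers had a median of -0.19 (14.3rd percentile); Cga was at -0.48, Tshb at -0.21, and Ghrhr at -1.49 on its brightest probe but -0.19 on the other.

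**Figure D3:**
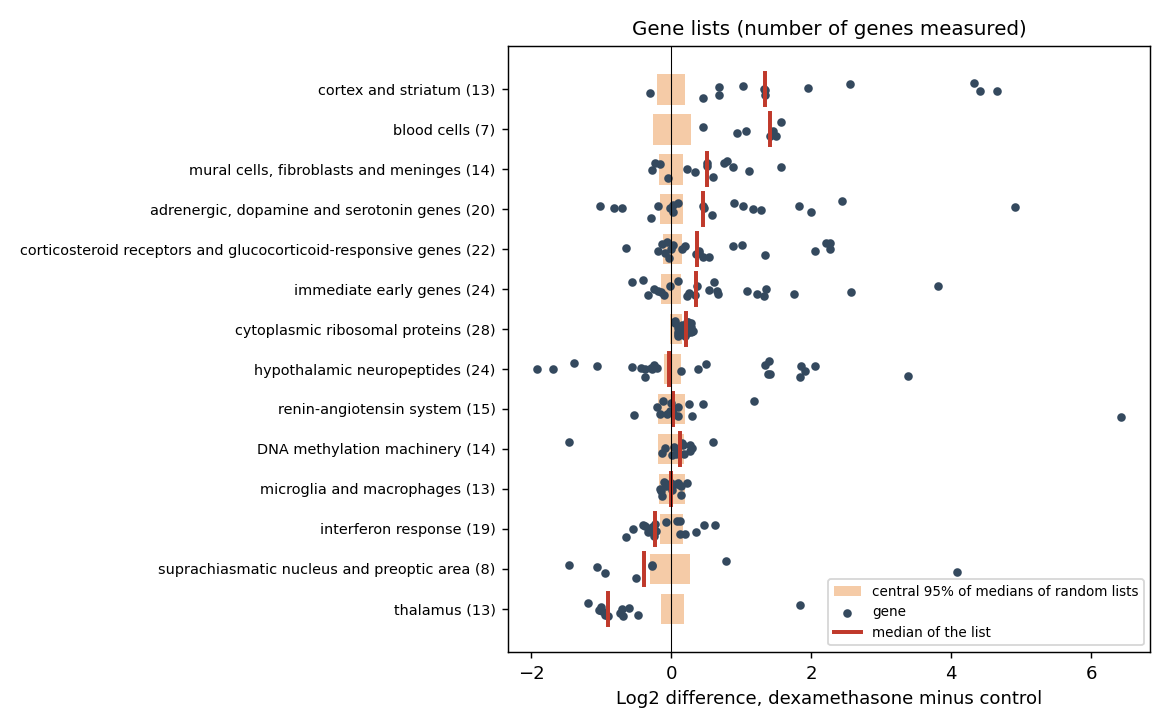
Log2 difference, dexamethasone minus control, of the measured genes of 14 lists (number of genes in parentheses). Points are genes, red bars list medians and shaded boxes the central 95% of medians of 10000 random lists; the medians of the cortex and striatum list (1.33) and blood list (1.40) lie above their boxes, and that of the thalamus list (-0.91) lies below.

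Some genes tied to corticosteroid action were at least 2-fold higher in the dexamethasone array, while others lay close to equality or lower. Nr3c2, the mineralocorticoid receptor, was 4.63-fold higher (2.21 on 1 probe and 2.22 on the other), and Nr3c1, the glucocorticoid receptor, was at 0.16. Fkbp5, a glucocorticoid-induced co-chaperone, was at 1.34, the metallothionein Mt2A at 2.05 and the sulfotransferase Sult1a1 at 1.01. Lcn2, the acute-phase lipocalin (2.27), and Zbtb16, a glucocorticoid-induced zinc finger gene (2.26), were dim and were at 0.85 and 0.76 with normexp. Other glucocorticoid-induced genes were at 0.89 (Mt1), 0.53 (Sgk1), 0.40 (Ddit4), 0.39 (Errfi1), 0.35 (Klf9), 0.19 (Nfkbia), -0.0066 (Tsc22d3), -0.04 (Per1), -0.19 (Dusp1) and -0.09 (Cdkn1a), and Hsd11b2, which inactivates corticosterone, was at -0.65. Of 22 measured genes 6 were at least 2-fold higher and 0 lower, 16 lay within 2-fold and 7 were below 0, with a median of 0.37 (100th percentile). Nr3c2 is also a gene of hippocampal neurons, and the cortex and striatum markers were higher in the same array (median 1.33). These animals were exposed before birth and measured at 12 weeks.

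Part of the monoamine and activity-induced genes were at least 2-fold higher in the dexamethasone array. Slc6a3, the dopamine transporter, was at 4.90 (3.17 with normexp), Adra1d, an alpha-1 adrenergic receptor, at 2.43 (spot SD 0.047), and Adra2c, an alpha-2 receptor, at 1.99 (0.80 with normexp). Of 20 measured adrenergic, dopamine and serotonin genes 7 were at least 2-fold higher and 1 lower, and 6 in all were below 0 (median 0.46, 100th percentile; 0.18 without background correction). Among immediate early genes, which neurons induce within minutes of activity, Egr4, a zinc finger transcription factor, was at 3.81 and Arc, a regulator of synaptic plasticity, at 2.57 (spot SD 0.053). Nr4a3, a nuclear receptor, was at 1.75 on its brightest probe but -0.62 on the other. Of 24 measured genes 7 were at least 2-fold higher and 0 lower, and 8 were below 0 (median 0.35, 100th percentile; 0.18 with normexp), beside the cortex and striatum markers at 1.33.

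Receptors for fast transmitters were higher for some members, with list medians near 0. Of 22 glutamate genes, Slc17a7, the vesicular transporter of cortical excitatory neurons (1.95, and 0.95 with normexp), and the receptor subunits Grin2a (1.66), Gria2 (1.51), Gria1 and Grin2b were at least 2-fold higher and 0 lower (median 0.02, 53.1st percentile; -0.14 to 0.07 over settings). Of 21 GABA genes 4 were at least 2-fold higher and 0 lower, among them the receptor subunit Gabra5 (1.47, and 0.98 with normexp) and the synthesis enzymes Gad1 (1.29) and Gad2; the median was 0.08 (80.1st percentile), with a range of -0.06 to 0.10 over scalings. Of 30 potassium and calcium channel genes 3 were past 2-fold upward, among them Cacna1h, a T-type calcium channel (1.74), and Kcnj6, an inward rectifier (1.24). Cacna1e (-1.32, with its other probe at 0.85) and Cacna1g were past it downward (median -0.05, 13.4th percentile). Of 18 sodium-handling genes, Scn7a, the sodium-level sensor channel of the brain, was at -1.38, past 2-fold. The epithelial sodium channel subunits Scnn1a and Scnn1g were at 0.47 and 0.46, and at 0.11 and -0.0082 with normexp (list median -0.05, 21.6th percentile; -0.10 to 0.07 over settings).

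Oxidative and immune genes mostly lay close to equality. None of 26 NADPH oxidase and antioxidant genes passed 2-fold: Gpx3, a secreted glutathione peroxidase, was at -0.67, Nos1, neuronal nitric oxide synthase, at 0.54 (0.14 with normexp) and Rac2, an oxidase subunit, at 0.44, with a median of 0.04 (60.4th percentile; -0.0088 to 0.05 over scalings). None of 21 cytokine, chemokine and NF-kappaB genes did, with Ccl5 at -0.51, Icam1 at 0.48 and Cxcl10 at 0.36 (median 0.04, 69.3rd percentile). Interferon-response genes had a median of -0.23 (0.295th percentile), with 12 of 19 lower and none past 2-fold; Ifit2 was at -0.65, Mx1 at -0.54 and the immunoproteasome gene Psmb8 at 0.63. Genes of antigen presentation had a median of 0.20 (98.5th percentile), with 12 of 15 higher: Cd74, the invariant chain, was at 0.89, the class II gene RT1-Da at 0.88 and RT1-N2 at -0.43. RT1 genes are a family of similar sequences, so their single values are uncertain.

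Genes of cell maintenance differed little. All 28 ribosomal protein genes were higher with the main scaling and at least 22 under every other scaling, by small amounts (median 0.21, 99.95th percentile, but 0.13 with quantile normalization and 0.11 with cyclic loess; Rpl5 0.30, Rpl3 0.30, Rpl7 0.29), and none passed 2-fold. Respiratory chain genes had a median of 0.09 (78.2nd percentile), which was -5.77e-05 with cyclic loess; Cox7c was at 0.32, Ndufs4 at 0.26 and Ndufa5 at 0.25, and none of 31 passed 2-fold. Heat shock and unfolded protein genes had a median of 0.08 (74.8th percentile), with Hspa1b, an inducible chaperone, at 1.28 (0.98 with normexp), Calr at 0.44 and Hsp90b1 at 0.43; 1 of 17 passed 2-fold. Clock genes had a median of -0.14 (4.88th percentile) with 15 of 19 lower and none past 2-fold. Among them were Npas2 (-0.62, with its other probe at -0.09), Rora (-0.47) and Ciart (-0.34). Histone modifiers had a median of -0.06 (16.7th percentile) with none of 18 past 2-fold: the methyltransferases Suv39h1 and Ezh2 were at -0.84 (0.53 on the other probe of Suv39h1) and -0.65, and the deacetylase Hdac3 at -0.24. Reference genes in common use had a median of -0.03 (13.3rd percentile), with Actb at 0.40, Tfrc at -0.34 and B2m at 0.33.

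Markers of blood and most markers of connective tissue were higher in the dexamethasone array. All 7 measured blood markers were higher and 5 at least 2-fold, with a median of 1.40 (100th percentile): the globin genes Hbb-b1 (1.57) and Hbb (2.83-fold) and the erythroid haem synthesis gene Alas2 (1.45) led them, with Hba-a1 and the neutrophil gene S100a8 also past 2-fold. The globin genes are near-identical copies, so their split is uncertain. Markers of mural cells, fibroblasts and meninges had a median of 0.51 (100th percentile), with 10 of 14 higher and 4 lower. The fibrillar collagens Col1a2 (2.97-fold) and Col3a1 (2.15-fold) were the 2 past 2-fold, and Col1a1 was at 0.88. Endothelial markers had a median of -0.03 (37.7th percentile), with Ly6e at 1.16, Emcn at -0.53 and Pecam1 at -0.37. Choroid plexus and ependymal markers had a median of 0.27 (99.8th percentile), led by Tmem212 (0.55), Clic6 (0.45) and Dynlrb2 (0.42).

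Glial and general neuronal markers differed less. Oligodendrocyte markers had a median of 0.23 (99.2nd percentile), with 12 of 13 higher: the myelin gene Mobp was at 0.69, the myelin lipid enzyme Ugt8 at 0.63 and Ermn at 0.47. Precursor markers had a median of 0.22 (97.6th percentile), with Bcas1 at 0.66 and the transcription factors Olig1 and Olig2 at 0.36 and 0.32. Astrocyte markers had a median of 0.12 (86.1st percentile), with the glutamate transporter Slc1a2 at 0.75, the filament gene Gfap at 0.73 and Slc7a10 at -0.61. Pan-neuronal markers had a median of 0.08 (66.4th percentile), with Map2 at 0.61, Elavl4 at -0.45 and Nefl at 0.38. Microglial markers had a median of -0.0045 (44.3rd percentile; -0.05 to 0.01 over scalings), with Aif1 at 0.22, Mrc1 at -0.16 and Cx3cr1 at 0.14. None of these glial and neuronal markers passed 2-fold on its brightest probe, though the other probe of Gfap was at 1.14. Over the 37 lists fixed in advance, 13 had a median above the central 95% of random lists and 3 below it. Several of these lists held genes on both sides of 0, among them the suprachiasmatic and preoptic list, with 2 genes higher and 6 lower.

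Some genes were well above background on 1 array alone, 254 in the dexamethasone array and 420 in the control array, of which 81 and 57 had a bound of at least 2-fold. Defb1, an antimicrobial defensin, was at least 19.0-fold higher in the dexamethasone array, Ffar3, a receptor for short-chain fatty acids, at least 14.97-fold, and Dmrt3, a transcription factor, at least 13.7-fold. Klk1c10, a kallikrein, was at least 9.22-fold lower, Epb41l5 at least 7.30-fold and Clec4b2, a lectin receptor, at least 4.95-fold. Tbr1, a cortical transcription factor, was well above background in the dexamethasone array alone, at a signal of 12.2.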

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

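The tests on probes with a GAA repeat were chosen after the low values of such probes had been seen, although the bounds for run length and for purine content were set before those values were looked up. Probes with no gene name were left out of the comparisons above. Of 5005 such probes measured on both arrays, 49 were at least 2-fold higher in the dexamethasone array and 259 (5.17%) at least 2-fold lower, against 2.62% of named genes. They stand out because a difference past 2-fold appears in data outside the gene-level comparison.

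A small part of the lower set shares a sequence, and the rest of it is not accounted for here. Of 48 measured probes, named or not, with a 12-base GAA repeat, 36 (75%) were at least 2-fold lower in the dexamethasone array and 0 higher, with a median of -2.02, against 3.03% lower among other probes. The difference fell with the length of the repeat (Spearman rho -0.566 over 195 probes with a run of 9 bases or more). These 195 take in the 48 repeat-bearing probes, a kind already seen to be low. The correlation is therefore no independent evidence of signal from RNA that pairs with the repeat, which stays possible. Probes with a run of 9 to 11 bases had a median of -0.08. Of these 147 probes 19.7% were at least 2-fold lower, against 2.92% for runs under 9. Repeat-bearing probes may not report the genes they are named for. On Flywch1 the repeat-bearing probe was at -2.21 and the other at -0.01, and on Apol7b they were at -2.23 and -0.45, though on Tcf7l2 the values were -1.06 and -0.91. Of 25 purine-rich probes without the repeat, 12 (48%) were at least 2-fold lower and 0 higher. Their median of -0.884 lay between the bounds set for and against base composition, so that explanation and the repeat cannot be told apart. A lower level of a repeat-bearing transcript after prenatal dexamethasone stays open as well with 1 array per group.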

How the results depend on the processing

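The counts without the telencephalic lists and without GAA-repeat probes were chosen after seeing the data; all others were planned. No paired analysis was possible because each group had 1 array, and for the same reason leaving out a replicate and other splits of the samples could not be run. Against 501 genes higher and 401 lower, the counts were 290 and 162 with normexp background correction, 286 and 165 without background correction, 954 and 890 with no filter on dim probes, 185 and 86 for bright genes alone, 1088 and 1207 at 1.5-fold, and 209 and 112 at 3-fold. The share higher among called genes was 55.5% in the main setting, 64.2% with normexp, 68.3% for bright genes, 51.7% with no filter on dim probes and 47.4% at 1.5-fold. Of the counts under the other settings, 14 were within 1.5 times the main ones, including 516 and 394 with quantile normalization or the deposited value table, 471 higher without the telencephalic lists and 394 lower without GAA-repeat probes. No scaling moved the median of all genes by over 0.1, which was close to fixed in advance because each scaling aligns the 2 arrays.

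Of the list medians under alternatives, 399 stayed within and 6 moved outside the bootstrap interval over the genes of the list. The exceptions were the respiratory chain list at 0.0073 with quantile normalization, -5.77e-05 with cyclic loess and 0.0078 in the deposited value table, and the ribosomal list at 0.13, 0.11 and 0.13; the cause was not tested. The bootstrap interval reflects the spread between the genes of a list. It is wide for mixed lists, so a median that stayed within it need not be stable. For the lateral hypothalamic list the interval ran from -0.94 to 1.91, while the median ranged from 0.13 to 1.20 over settings. Medians of the GABA, glutamate, sodium, NADPH oxidase, cytokine, microglial, endothelial, arcuate and respiratory chain lists took both signs over the settings. Of the named genes' values, 1101 moved by less than the SD of repeated spots, 303 moved by more, and Cacna1e, alone among those past 2-fold, changed sign, to 0.47 with normexp, under which its other probe became the brighter. Among genes within 2-fold, some near 0 changed sign too, as did Scnn1g (-0.0082 with normexp). Signal over background is a further limit beside the number of arrays: dim genes such as Agtr1a, Lcn2 and Zbtb16 lost their 2-fold call under both other background treatments, which leave or add a constant that shrinks differences at low signal.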

Other observations

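The 5 lists below were written after the first differences had been seen, and the tests on them and on Agtr1a were chosen then; only the bound for the second telencephalic list was set before its values were looked up. Pallial neuron genes had a median difference of 1.22 (11 of 18 at least 2-fold higher in the dexamethasone array, 0 lower), led by Fezf2 (5.32), Kcnv1, a potassium channel modifier (4.60), and Emx2, a cortical patterning gene (3.99). Hippocampal genes had a median of 0.71 (5 of 12 at least 2-fold higher), with Cabp7, a calcium-binding protein, at 3.51 and Wfs1, a gene of the CA1 field, at 2.10; Fibcd1, Dsp and Pou3f1 were the others. Striatal genes had a median of 0.46 (2 of 12 at least 2-fold higher, among them Drd2), while the striatal phosphodiesterase Pde10a was at -0.02. Hypothalamic genes had a median of -0.24, with 2 of 18 at least 2-fold higher (Crh and Dlk1) and 2 lower (Avp and Oxt). Some genes stand in more than 1 list, and every gene counted as measured was well above background in the control array too.

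The first pattern is the excess of telencephalic genes. Whether the dexamethasone sample was taken wholly from another region cannot be decided here, since the bound was chosen after the values were seen. Avp, Oxt, Crh, Trh and Sim1 were all well above background in that array, as were 78.2% of all probes. The lowest of these 5, Avp, stood at 26.6% of its control level. Among measured genes Avp ranked at the 58.1st percentile in the dexamethasone array and at the 78.6th in the control array. How far neighbouring regions give such levels was not analysed here, so a wholly or largely neighbouring origin of the dexamethasone sample is not excluded. A share of telencephalic tissue in that sample may account for the excess: the second telencephalic list had a median of 0.482 with 77.8% of 18 genes higher (100th percentile), just short of the bounds of 0.5 and 80% set for it and above the 0.2 set against it. Lower thalamic markers (-0.91) and higher blood markers (1.40) also differ between the samples. Markers of neighbouring regions gave high signal in the control array too. There Prkcd of the thalamus stood at the 98.6th percentile of measured genes and Pmch of the lateral hypothalamus at the 90.8th. The control sample can therefore not be taken as the nucleus alone. A change within cells of the nucleus after prenatal dexamethasone stays open and cannot be told apart from a different dissection with 1 array per group.

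The other pattern is the higher Agtr1a signal. Background subtraction as the source of its direction is argued against, since without it the difference was 0.471 (spot SD 0.101). The fold then no longer reached 2 because the uncorrected signal contains background on both arrays. The spot SD does not measure a background offset shared by all spots of an array, so it cannot exclude such an offset. Signal from Agtr1b on the Agtr1a probe stays open: Agtr1a exceeded Agtr1b by 0.733, but both probes are dim and Agtr1b had 1 spot. A different mix of tissue stays open as well, since Agtr1a levels in the neighbouring regions were not analysed here. Of genes of like signal, 7.71% differed at least as much either way, a share that does not tell tissue mix from noise at low signal. A different mix of tissue cannot be told apart from an effect of prenatal dexamethasone with these arrays.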
